A study of Xenopus laevis with 54 samples.

How the data were processed

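The series measured messenger RNA in early embryos of the frog Xenopus laevis, a species whose genome holds an L and an S copy of many genes, and in unfertilized eggs. Per the labels' protocols, embryos were injected at the single-cell stage with 10 nl of 50 mM 5-ethynyl uridine (EU), a uridine analog that is built into newly made RNA, for a final concentration of about 0.5 mM. They were cultured and collected at 5, 6, 7, 8 and 9 hours post fertilization (hpf). EU-RNA was biotinylated by click chemistry and captured on streptavidin beads, which gave a bead fraction and a flowthrough fraction that was not captured, and libraries were made after depletion of ribosomal RNA, per the labels. The 54 libraries were 20 bead, 20 flowthrough and 12 total RNA libraries of embryos and 2 egg libraries. Experiment 1 held replicates 1 and 2 of bead, flowthrough and total RNA at all 5 times, and experiment 2 held replicates 3 and 4 of bead and flowthrough RNA at all 5 times, of total RNA at 5 hpf, and both egg libraries. Total RNA at 6 to 9 hpf therefore came from experiment 1 and eggs from experiment 2.

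The authors deposited a table of 50489 genes by 54 libraries whose values are a score, whole numbers left after DESeq2 normalization and rounding, per the submitters' processing notes. Those notes name Salmon 0.12.0 and DESeq2, and the genome build and annotation are not given in the sources used here. The table also held 1 column that names no library of the series, which was not used. Reads per library cannot be read from rounded normalized values, so no counting interval was computed. Column totals were 7376513 to 8806052 in bead, 7455643 to 7765802 in flowthrough and 7869490 to 8757424 in total RNA libraries of experiment 1. In experiment 2 they were 8175480 to 15200969 in bead, 7692598 to 8090104 in flowthrough, 8243126 to 8405525 in total RNA and 8405085 to 8510493 in egg libraries. Such totals are set by the scaling and are not depths. A sign of low depth or of low recovery of RNA was the number of genes above 0, which does not by itself separate them. It was 12814 to 18990 in the bead libraries of experiment 2 and 23212 to 28348 in those of experiment 1. The smallest value above 0 was 9 in the bead library of 6 hpf, replicate 3, and 2 and 3 in those of 8 and 9 hpf, replicate 4, against 1 in every bead library of experiment 1. Genes with high levels in other libraries were listed at 0 in bead libraries of experiment 2, so a value of 0 is reported only as listed, and no fold is given against a group whose libraries were all at 0.

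The planned count tests were not run because the values are not counts. The test planned for normalized values was used, limma-trend (limma 3.58.1 with statmod 1.5.0 in R 4.3.3, trended and robust empirical Bayes) on log2(value + 1). A fold change is therefore on the log2(value + 1) scale, which understates changes of low genes. Genes with a value of at least 10 in at least as many libraries as the smallest group of the fit were tested. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene was called when its adjusted p was under 0.05 and its change at least 2-fold. All groups of a fraction shared 1 estimate of spread, with a term for experiment, and bead against flowthrough fits also had a term for experiment by fraction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

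Before the data were examined, the comparisons, tests, alternatives, gene lists and the rule for named genes were fixed. The rule took, for the main comparisons, the 8 called genes with the largest positive and the 8 with the largest negative change among genes with a proper symbol, a mean of at least 50 in the higher group and no overlap between the groups, then up to 4 called members of each list with the smallest adjusted p and up to 2 members that were not called, and the 6 genes with the largest change of each onset class. About 20 to 30 of these were to be named per comparison. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. They were nodal ligands and early Wnt targets, mesendoderm transcription factors, signals of the organizer and marginal zone, BMP-responsive and ventral genes, ectoderm genes, Pou5f3, Sox and partner factors, immediate early genes, cell cycle regulators, maternal messages known to be cleared, germ plasm messages, ribosomal proteins, histones, translation factors, splicing factors, nuclear genes of the respiratory chain, RNA polymerase II and Mediator subunits, chromatin and DNA methylation genes, and control lists of late differentiation markers and of ovary, follicle and blood markers. The lists of mitochondrially encoded genes and of the miR-427 cluster matched 0 genes of the table. The ribosomal list also matched kinases named rps6k, and a list without them was added after the data were seen. Some genes were near-identical copies whose reads the counting could have split, including tRNA genes with equal values in every library, and these are uncertain, as are L and S copies of similar sequence.

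The series' design text gives each replicate number to 1 clutch, so the numbers pair bead, flowthrough and total RNA libraries. Over 52 entries of same-numbered library pairs the correlation of their deviations from the group means was 0.0553 to 0.639 across genes, which are not independent replicates. The 4 pairs of bead and flowthrough RNA at 9 hpf were entered again for the change of the bead to flowthrough ratio. Fewer than 52 pairs are therefore distinct. A fit with the replicate number as a block was run beside each result. Alternatives also changed the scaling, filter, pseudocount, fold threshold, experiment term, libraries in the fit and experiment, and left out each library in turn. Library weights, a term for odd against even replicates, averages of replicates 1 with 3 and 2 with 4, fits without the bead libraries of experiment 2, egg fits on experiment 2 alone, and settings added for onset classes, overlaps, homeologs and lists were chosen after seeing the data.

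The tests were tried on simulated data in which 200 genes were changed by 2, 4, 8 or 16-fold, in 5 runs per comparison. The simulation was rebuilt, and the criterion that it had to meet was changed, after it first failed. At first the simulated bead and flowthrough baselines differed, and after that was mended 1 run of total RNA at 5 hpf against eggs still called 1 gene in the wrong direction. The criterion was then applied to simulations with equal spread in all libraries, where 0 genes were called in the wrong direction and 3.22% to 6.04% of calls were unchanged genes. With the spreads of the data, unchanged genes made up 1.64% of calls for bead RNA at 9 against 5 hpf, 1.56% for flowthrough RNA, 6.78% for total RNA, 19.4% and 21.2% for bead against flowthrough at 5 and 9 hpf, and 23.7% for total RNA against eggs. Adjusted p-values of the last 3 comparisons are therefore too small. Apart from the changed genes, simulated spread and baseline within a fraction and experiment were the same at all times. In the data, 0.303% and 3.49% of 11548 abundant genes were listed at 0 in bead replicates 3 and 4 of 5 hpf. At 9 hpf the shares were 12.1% and 21.8%. The 1.64% therefore does not cover lower calls in bead RNA that rest on such values of 0. Of genes changed 4-fold, 42.8% were called for bead RNA at 9 against 5 hpf, 93.2% for flowthrough RNA, 81.2% for total RNA, 64.8% for bead against flowthrough at 9 hpf and 80% for total RNA against eggs. In simulated bead data 3 of 99 lists with no shift had p under 0.05 in the camera test. Genes were drawn independently there, so this does not show how the list test behaves when members of a list vary together.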

Results

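RNA was followed from 5 to 9 hpf in Xenopus laevis embryos, the hours of the blastula in which the embryo's own genome is switched on, and compared with the RNA of unfertilized eggs. The bead fraction was captured by its EU label, which marks RNA made after fertilization, and the flowthrough is RNA that was not captured. The labels name no embryos without EU put through the capture, so unlabelled RNA on the beads was not measured. The maternal message btg4.L was at 683, 634, 889 and 1246 on the beads at 5 hpf and at 644, 512, 613 and 619 in flowthrough. Each group of bead or flowthrough RNA held 4 libraries, 2 from each of 2 experiments. Total RNA held 4 libraries at 5 hpf and 2 at each later time, and eggs held 2. The series' design text describes the replicates as separate clutches.

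Detection differed between the experiments. Bead libraries of experiment 2 had values above 0 for 12814 to 18990 genes, against 23212 to 28348 in experiment 1, 21965 to 25064 in flowthrough and 23053 to 28666 in total RNA libraries. Of 11548 abundant genes, 21.8% were listed at 0 in the bead library of 9 hpf, replicate 4, 17.9% in that of 8 hpf, replicate 4, and 12.1% in that of 9 hpf, replicate 3.

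**Figure D1:**
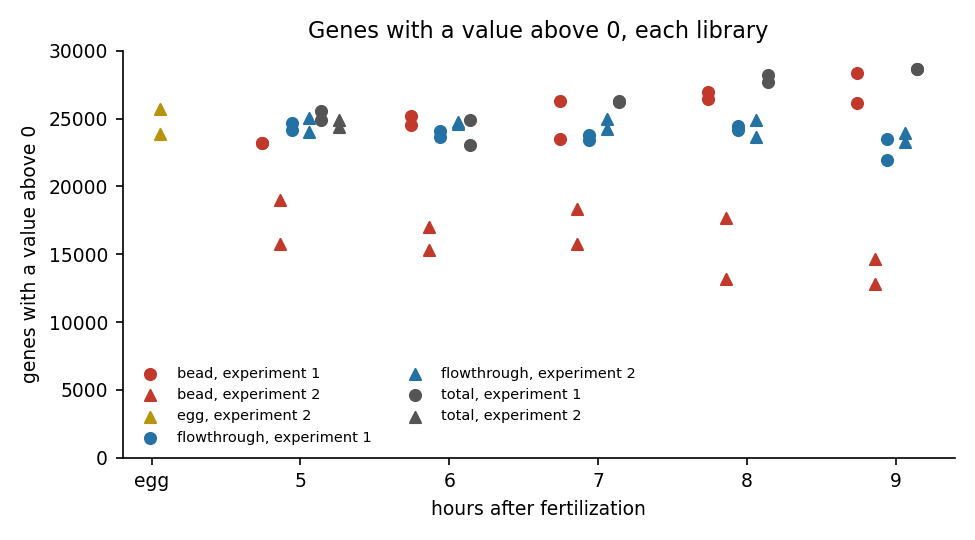
Number of genes with a value above 0 in each library, by fraction (color) and experiment (shape), for eggs and for each time in hours post fertilization. Bead libraries of experiment 2 lie between 12814 and 18990 genes, below every other library.

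Bead RNA gained a large set of developmental regulators between 5 and 9 hpf. At 9 hpf 1208 genes were higher and 296 lower than at 5 hpf among 20703 tested, and 620 of the higher genes had risen by at least 32-fold on the log2(value + 1) scale. The homeobox gene ventx2.2.L, a target of BMP signaling, was listed at 0 in the 4 libraries of 5 hpf and reached 3709 ± 805 at 9 hpf (SD, n = 4). The POU-family factor pou5f3.2.L rose from 672 ± 172 to 19124 ± 311 (SD, n = 4), a log2 change of 4.87 ± 0.21 (SE, adjusted p = 1.71e-12), and its S copy pou5f3.2.S rose by 6.89 ± 0.37 (SE, adjusted p = 4.48e-11). The mitotic kinesin gene kif11.S dropped by 1.53 ± 0.19 on the log2 scale (SE, adjusted p = 5.48e-06, or 0.0542 in experiment 2 alone).

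**Figure D2:**
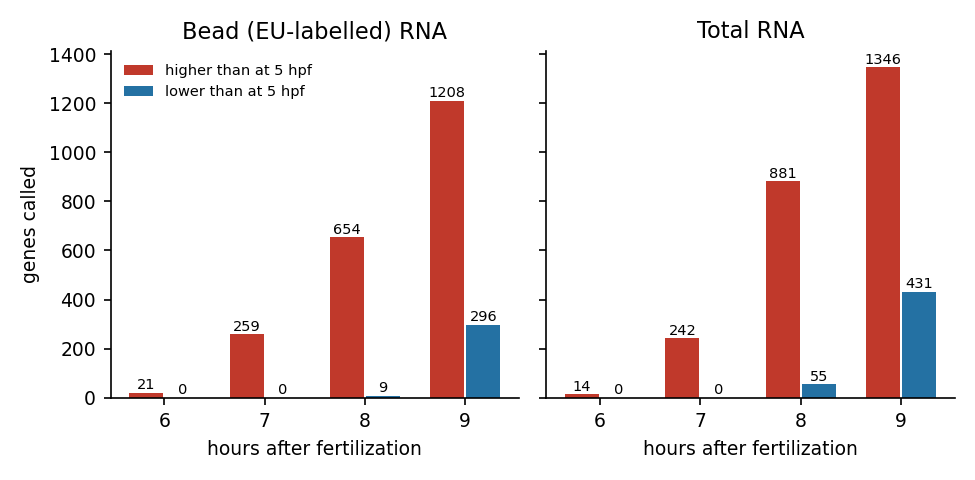
Number of genes called higher or lower than at 5 hpf in bead and in total RNA at each later time, in hours post fertilization. Higher calls in bead RNA go from 21 at 6 hpf to 1208 at 9 hpf, and in total RNA from 14 to 1346.

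The rise began with a few genes. At 6 hpf 21 genes were higher, at 7 hpf 259 and at 8 hpf 654, while limma called 0, 0 and 9 genes lower. In the limma fit 181 and 201 genes had an unadjusted p under 0.05 for lower values at 6 and 7 hpf. That is fewer than chance would give among 20703 genes with no change. Higher values were as few at 6 hpf, with 178 genes, so the shortfall does not show that no gene fell. Genes higher from 6 hpf onward included gs17.L, mix1.L, bix1.2.L, foxh1.2.L, ventx2.2.S and foxi4.2.S. The homeobox gene mix1.L, a regulator of mesendoderm, was listed at 4, 12, 34 and 0 at 5 hpf, at 77, 104, 77 and 76 at 6 hpf, and reached 6877 ± 1340 at 9 hpf (SD, n = 4), with a log2 change of 9.94 ± 0.68 (SE, adjusted p = 1.89e-09). The early zygotic gene gs17.L went from 6, 3, 0 and 0 to 4276 ± 1353 (SD, n = 4). By the first time from which a gene stayed called, 21 genes were in the class of 6 hpf, 224 of 7 hpf, 358 of 8 hpf and 605 of 9 hpf. The 224 became 128 or 146 without replicate 1 or 4. The classes of 6 and 7 hpf were larger in experiment 1 alone, and all classes were smaller in experiment 2 alone. They date the calls, which depend on the libraries used, and not the start of transcription. The 7 hpf class included ventx2.2.L, ventx2.1.L, has2.L, an enzyme that makes hyaluronan, and foxa4.L, a forkhead factor of the dorsal midline. The T-box genes eomes.S and eomes.L and the homeobox genes mixer.S and mixer.L were in the 8 hpf class, and flrt3.S, gatm.L and the Notch ligand dll1.S in the 9 hpf class. In experiment 2 alone mixer.S, mixer.L, gatm.L and dll1.S were not called at 9 hpf (adjusted p = 0.0542, 0.0665, 0.143 and 0.123).

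**Figure D3:**
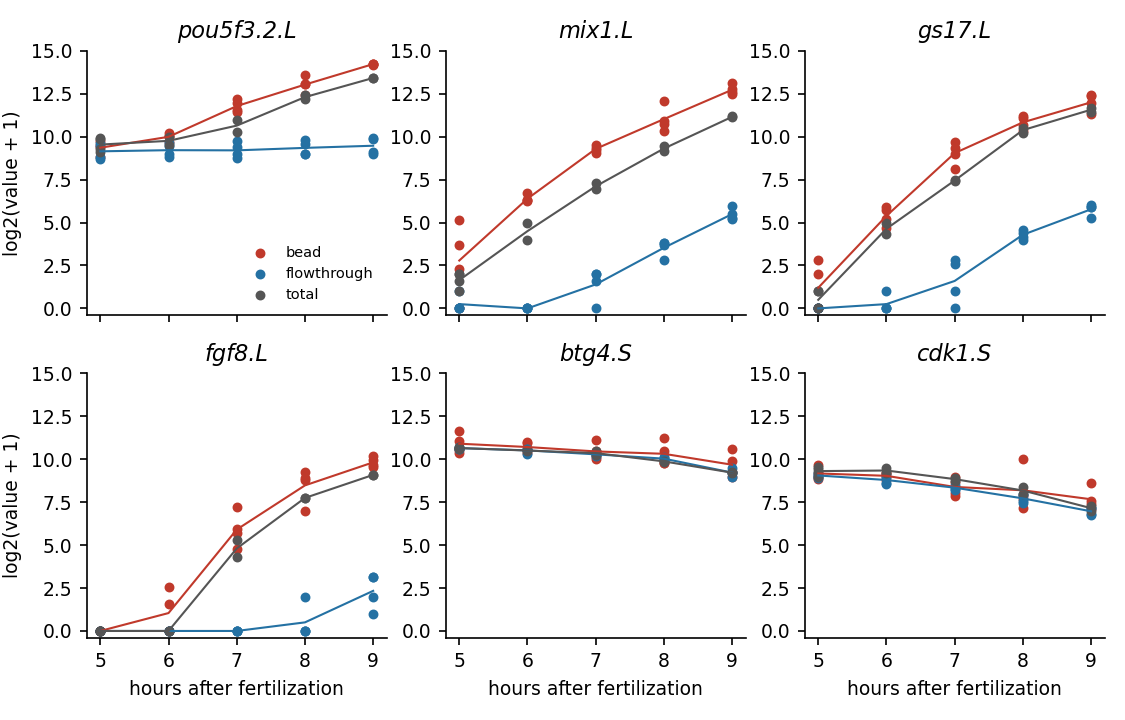
Values of 6 genes, as log2(value + 1), against hours post fertilization in bead, flowthrough and total RNA libraries; points are libraries and lines join means. mix1.L, gs17.L and fgf8.L rise from low values in bead and total RNA, pou5f3.2.L rises in both from a level already present at 5 hpf, and btg4.S and cdk1.S lie lower at 9 than at 5 hpf in total and flowthrough RNA.

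The lists of early embryonic regulators rose together in bead RNA at 9 hpf. Of 18 nodal ligands and early Wnt targets tested 10 were higher (13 adjusted over the list alone), of 45 mesendoderm factors 31 (33 adjusted over the list alone), of 29 organizer and marginal zone signals 14 (20), and of 30 BMP-responsive and ventral genes 18 (18), with 0 lower in each. With an estimated correlation their camera adjusted p-values were 7.97e-05, 1.07e-05, 2.09e-05 and 4.83e-06. The nodal ligand nodal2.L was listed at 0 at 5 hpf and at 272 ± 96.1 at 9 hpf (SD, n = 4; adjusted p = 0.0903 in experiment 2 alone), and the signal fgf8.L went from 0 in the 4 libraries to 914 ± 185 (SD, n = 4). Ectoderm genes had 21 of 43 higher and 1 lower (adjusted over the list alone 21 and 5; adjusted p = 0.00126 with an estimated correlation). Pou5f3, Sox and partner factors had 10 of 30 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.0325 with an estimated correlation), including sox3.S, which rose by 2.00 ± 0.16 (SE, adjusted p = 1.6e-08).

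**Figure D4:**
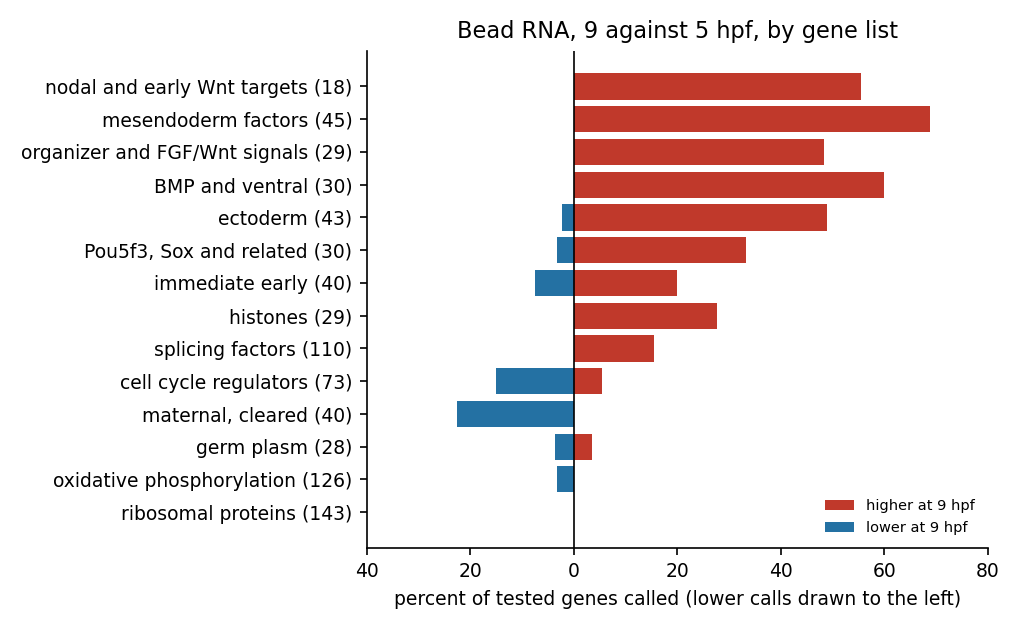
Percent of the tested members of each gene list called higher (right) or lower (left) in bead RNA at 9 against 5 hpf, with the number tested in parentheses. Mesendoderm factors stand highest, with 31 of 45 members higher, and ribosomal proteins have 0 of 143 called.

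Histones and splicing factors also moved up in bead RNA. Of 29 histone genes 8 were higher (9 adjusted over the list alone; adjusted p = 0.00452 with an estimated correlation), and of 110 splicing factors 17 were higher (18 higher and 3 lower adjusted over the list alone; adjusted p = 0.000212 with an estimated correlation). The histone gene h3c14.L rose by 2.60 ± 0.26 (SE, adjusted p = 1.33e-06) and the RNA-binding protein gene hnrnpdl.L by 2.77 ± 0.24 (SE, adjusted p = 1.26e-07). Both lost the call without the experiment term (adjusted p = 0.279 and 0.0946). The chromatin protein gene hmgb2.L rose by 1.81 ± 0.16 (SE, adjusted p = 2.18e-07), which shrank to 0.32 under quantile normalization (adjusted p = 0.0728). The maintenance DNA methyltransferase gene dnmt1.S fell by 1.12 ± 0.12 on the log2 scale (SE, adjusted p = 7.39e-07, or 0.0795 in experiment 2 alone). The chromatin list as a whole had 4 of 45 higher and 1 lower, the same adjusted over the list alone. Its camera adjusted p was 0.0653 (0.062 with an estimated correlation), 0.0367 upward with the replicate block and 0.00421 downward under quantile normalization.

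Maternal messages known to be cleared fell in bead RNA, with 9 of 40 lower and 0 higher (16 lower adjusted over the list alone; adjusted p = 0.0122 with an estimated correlation). The gene btg4.S, whose product recruits a deadenylase to maternal messages, fell by 1.22 ± 0.22 on the log2 scale (SE, adjusted p = 0.000507). It lost the call without the experiment term (adjusted p = 0.0847) and in experiment 2 alone (0.229). Of 73 cell cycle regulators 11 were lower and 4 higher (14 and 5 adjusted over the list alone; adjusted p = 0.0792 with an estimated correlation). The mitotic kinase gene plk1.S changed by -1.45 ± 0.20 (SE, adjusted p = 2.12e-05), or by -0.97 in experiment 1 alone, while the phosphatase gene cdc25b.L was at 1259 ± 394 at 9 hpf (SD, n = 4) and rose by 8.84 ± 1.08 (SE, adjusted p = 5.03e-06, or 0.0542 in experiment 2 alone). Immediate early genes had 8 of 40 higher and 3 lower (9 and 4 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation). Respiratory chain genes had 4 of 126 lower (0 adjusted over the list alone; adjusted p = 0.178 with an estimated correlation). Of 143 ribosomal protein genes limma called 0, and 0 adjusted over the list alone (adjusted p = 0.572 with an estimated correlation; 0.482 for the 133 without the kinases). At the preset correlation the list had an adjusted p of 0.0627, and 0.0481 without the kinases. Germ plasm messages had 1 of 28 higher and 1 lower (1 and 2 adjusted over the list alone; adjusted p = 0.314), translation factors 5 of 93 and 1 (5 and 1; adjusted p = 0.796), RNA polymerase II and Mediator subunits 3 of 102 and 0 (3 and 0; adjusted p = 0.564, or 0.0332 downward under quantile normalization). Late differentiation markers had 1 of 7 higher (1; adjusted p = 0.513), and ovary, follicle and blood markers 0 of 4 (0; adjusted p = 0.564).

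The size of the largest named drops in bead RNA rests on libraries of experiment 2 in which these genes were listed at 0. At 9 hpf garem1.L was at 289, 420, 0 and 0 in replicates 1 to 4, against 667, 797, 465 and 467 at 5 hpf. The cell cycle regulator fzr1.L was at 248, 308, 0 and 0 against 562, 594, 413 and 352, and chmp1b.L at 60, 34, 0 and 0 against 247, 247, 298 and 151. These 3 lost their calls without the experiment term (adjusted p = 0.0720, 0.0554 and 0.0517), without all of replicate 3 (0.125, 0.0970 and 0.143) and without replicate 4 (0.137, 0.0957 and 0.0993). Their log2 changes were -4.97, -4.82 and -5.08 without the term and -3.67, -3.53 and -4.03 without replicate 3. All 3 kept the call in experiment 1 alone. In experiment 2 alone garem1.L and fzr1.L kept it, and chmp1b.L did not (adjusted p = 0.135). Without bead replicate 3 of 9 hpf the values were 0.0571 for garem1.L and 0.0519 for chmp1b.L, without its replicate 4 0.0638 for garem1.L, and without bead replicate 3 of 5 hpf 0.0650 for chmp1b.L. Of the 296 lower genes 156 were listed at 0 in at least 1 bead library of experiment 2 at 9 hpf. In experiment 1 alone 1635 genes were higher and 364 lower, and in experiment 2 alone 224 and 56. At 6, 7 and 8 hpf the higher counts were 32, 534 and 1050 in experiment 1 and 2, 21 and 55 in experiment 2. Quantile normalization moved the share of higher genes among the calls at 9 hpf from 80.3% to 69.4% (1277 higher, 562 lower) and the median change of all genes from -0.33 to -0.22. Higher counts fell to 13 at 6 hpf without bead replicate 2 of that time, and to 145 and 166 at 7 hpf without all libraries of replicate 1 or 4. The 9 lower genes of 8 hpf became 24 without bead replicate 2 of that time and 3 without its replicate 4, 4 and 2 without bead replicate 3 or 4 of 5 hpf, and 3, 4 and 0 without all of replicate 1, 3 or 4. The 0 of 7 hpf became 3 without bead replicate 1 of 5 hpf and 1 without bead replicate 2 of 7 hpf or all of replicate 2. The 296 lower genes of 9 hpf became 571 and 622 without bead replicate 1 or 2 of 9 hpf, 171 and 187 without its replicate 3 or 4, 91 and 106 without bead replicate 3 or 4 of 5 hpf, and 87 and 112 without all libraries of replicate 3 or 4.

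Bead and flowthrough RNA were compared at each time to ask which RNAs were captured. At 9 hpf 2014 genes were higher on the beads and 4075 lower among 21544 tested. Of the named genes with the largest differences znf750.L was at 1537 ± 454 on the beads (SD, n = 4), with a log2 difference of 9.28 ± 0.72 (SE, adjusted p = 5.9e-12), and grhl3.S and dlx5.S were at 920 ± 221 and 697 ± 143 on the beads (SD, n = 4), with log2 differences of 9.03 ± 0.93 (SE, adjusted p = 2.42e-09) and 8.77 ± 0.81 (SE, adjusted p = 2.07e-10). The signal fgf8.S, the adhesion protein gene flrt3.L, the receptor gene lpar6.L and cdc25b.L were higher by 8.98 ± 0.56, 8.86 ± 0.77, 8.74 ± 0.50 and 8.84 ± 0.82 (SE). In flowthrough flrt3.L and dlx5.S were at 1 and 5 in replicate 3, and lpar6.L and grhl3.S at 1 and 8 in replicate 4. All 4 of these genes were at 0 in the other flowthrough libraries of 9 hpf, so the size of their differences depends on the pseudocount. The level of pou5f3.2.L was 19124 ± 311 on the beads and 738 ± 238 in flowthrough (SD, n = 4), a log2 difference of 4.75 ± 0.27 (SE, adjusted p = 3.97e-15).

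Of 18 nodal ligands and early Wnt targets 15 were higher on the beads, of 45 mesendoderm factors 36, of 29 organizer and marginal zone signals 25 and of 30 BMP-responsive and ventral genes 19, with 0 lower in each (15, 37, 25 and 19 adjusted over the list alone; adjusted p = 2.19e-07, 2.8e-07, 1.91e-07 and 1.25e-08 with an estimated correlation). Examples are nodal2.L, foxa4.L, the secreted antagonist cer1.S and the BMP target id3.L, with log2 differences of 7.78 ± 0.51, 8.35 ± 0.62, 7.72 ± 0.68 and 7.21 ± 0.57 (SE). In flowthrough nodal2.L was at 1 in replicate 4 and cer1.S at 6 in replicate 3, against 0 in the others, so the size of these 2 differences depends on the pseudocount. Ectoderm genes had 23 of 43 higher and 3 lower (23 and 4 adjusted over the list alone; adjusted p = 5.8e-05 with an estimated correlation), among them sox3.S with 1.92 ± 0.12 (SE). Pou5f3, Sox and partner factors had 10 of 30 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.0626 with an estimated correlation). Splicing factors had 18 of 110 higher and 15 lower (18 and 16 adjusted over the list alone; adjusted p = 0.00101 upward with an estimated correlation, although the mean was -0.02, and 0.592 under quantile normalization). The chromatin list had 4 of 45 higher and 2 lower (4 and 2 adjusted over the list alone), with an adjusted p of 0.000892 upward, 0.494 in experiment 1 alone and 3.44e-05 downward under quantile normalization. Its member ep300.L differed by 1.14 ± 0.08 (SE), by 0.63 in experiment 1 alone and by -0.27 under quantile normalization. For hnrnpa2b1.L the difference of 1.63 ± 0.09 (SE) became 0.66 under quantile normalization. The difference of srsf4.L was 2.75 ± 0.18 (SE), or 0.75 in experiment 1 alone, and that of the RNA polymerase II subunit gene polr2a.L was 2.19 ± 0.18 (SE), 0.65 in experiment 1 alone and 0.52 under quantile normalization. Without the experiment term srsf4.L and polr2a.L were not called (adjusted p = 0.0683 and 0.0972).

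Genes lower on the beads at 9 hpf included 43 of 144 ribosomal protein genes and 43 of 129 respiratory chain genes, with 1 and 2 higher (43 lower in each adjusted over the list alone; adjusted p = 0.344 and 0.259 with an estimated correlation), and 11 of 40 cleared maternal messages (13 adjusted over the list alone; adjusted p = 0.136 with an estimated correlation). Cell cycle regulators had 8 of 73 higher and 12 lower (8 and 12 adjusted over the list alone; adjusted p = 0.221, or 0.00678 downward under quantile normalization). Immediate early genes had 11 of 42 higher and 4 lower (11 and 5 adjusted over the list alone; adjusted p = 0.136 with an estimated correlation). Of the cell cycle genes ccna1.S differed by -1.53 ± 0.19, ccnb2.L by -1.24 ± 0.18 and wee1.L by 3.31 ± 0.44 (SE); ccna1.S was at -0.81 and ccnb2.L at -0.10 in experiment 1 alone, and ccnb2.L lost the 2-fold difference without bead replicate 4 (-0.98) or all of replicate 4 (-0.96). The lower genes with the largest differences that the naming rule took were listed at 0 in both bead libraries of experiment 2. The vesicle coat gene sar1a.S was at 458, 467, 0 and 0 on the beads and 617, 493, 628 and 501 in flowthrough, pef1.S at 431, 371, 0 and 0 against 590, 633, 450 and 603, uqcrfs1.S at 282, 254, 0 and 0 against 531, 355, 412 and 365, and cbx2.S at 424, 351, 0 and 0 against 474, 455, 540 and 499. In experiment 1 alone 1780 genes were higher and 72 lower, and in experiment 2 alone 1651 and 4160. Without the bead libraries of experiment 2, a fit chosen after seeing the data, 138 were lower. Quantile normalization moved the higher share from 33.1% to 51.0% (2296 higher, 2204 lower) and the median from -0.69 to -0.28, and the lower count was 2538 without bead replicate 4 and 1511 without all of replicate 4. In simulated data with these spreads 21.2% of calls were unchanged genes. The simulation gave bead and flowthrough the same baseline within each experiment. It therefore holds no loss shared by the genes of the experiment 2 bead libraries, and 21.2% is not an upper limit for the lower calls.

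At earlier times the counts of genes higher and lower on the beads than in flowthrough were 94 and 316 at 5 hpf, 198 and 537 at 6 hpf, 730 and 657 at 7 hpf, and 1419 and 1784 at 8 hpf. With library weights, chosen after seeing the data, the lower counts were 2452, 2196, 2231, 2732 and 2479 at 5 to 9 hpf, so their rise with time depends on the weighting. The lower counts in experiment 1 alone were 6, 8, 16 and 19, and 348, 746, 712 and 1841 in experiment 2 alone. The higher counts were 17, 75, 641 and 1173 in experiment 1 and 305, 381, 680 and 1181 in experiment 2. The higher shares of 22.9%, 26.9%, 52.6% and 44.3% became 50.8% (127 and 123), 63.6% (304 and 174), 75.6% (1028 and 331) and 64.8% (1718 and 934) under quantile normalization, which moved the median of all genes from -0.28, -0.29, -0.29 and -0.49 to 0.01, -0.01, -0.11 and -0.21. Leaving out any 1 flowthrough library of the same time gave lower counts of 151 to 187 at 5 hpf, 237 to 299 at 6 hpf, 351 to 367 at 7 hpf and 933 to 1044 at 8 hpf. Without bead replicate 4 they were 194, 323, 386 and 752, and without bead replicate 3 they were 604 at 5 hpf and 3091 at 8 hpf. Without all of replicate 4 they were 107, 173, 235 and 400, without replicate 1 134, 246 and 297 at 5 to 7 hpf, without replicate 2 130, 246 and 370, and without replicate 3 277 at 6 hpf. The 94 higher genes at 5 hpf became 58 without replicate 4. The bead to flowthrough ratio rose from 5 to 9 hpf for 992 genes and fell for 35 in the test of the difference between the changes. In experiment 1 alone these were 1180 and 7, and in experiment 2 alone 331 and 267. The 35 moved to between 1 and 505 when any of the 20 libraries or replicate numbers was left out.

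Flowthrough RNA lost cell cycle messages and maternal messages known to be cleared from 5 to 9 hpf. Of 19277 genes tested 759 were lower at 9 hpf and 39 higher, or 63 higher with the replicate block. Quantile normalization gave 61 higher and 476 lower and moved the median of all genes from -0.04 to 0.07. The gene btg4.S fell from 1604 ± 43.1 to 600.0 ± 89.2 (SD, n = 4), a log2 drop of 1.43 ± 0.08 (SE, adjusted p = 3.58e-10), and btg4.L fell by 2.04 ± 0.11 (SE, adjusted p = 3.58e-10). The kinase gene cdk1.S, which drives entry into mitosis, fell by 2.09 ± 0.14 on the log2 scale (SE, adjusted p = 5.93e-09). The mitotic kinase gene aurka.L, the cyclin gene ccnb5.L and pbk.L changed by -1.67 ± 0.09, -1.32 ± 0.09 and -1.94 ± 0.10 (SE). The largest drops that the naming rule took were those of arl6ip1.L, arl3.S, prkab1.L, a subunit of the energy-sensing kinase AMPK, nfkbia.L, the inhibitor of NF-kappaB, and the spindle checkpoint gene mad2l1.L, with log2 changes of -3.75 ± 0.55, -2.88 ± 0.41, -2.85 ± 0.28, -2.62 ± 0.25 and -2.61 ± 0.38 (SE).

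Of 72 cell cycle regulators 11 were lower in flowthrough RNA and 0 higher, of 40 cleared maternal messages 11 and 0, and of 35 immediate early genes 11 and 0 (11, 11 and 13 lower adjusted over the list alone; adjusted p = 0.000441, 0.00569 and 0.047 with an estimated correlation). Immediate early genes that fell included fos.S, ccn1.L and junb.L, with log2 changes of -1.88 ± 0.22, -1.96 ± 0.26 and -1.58 ± 0.23 (SE). Of 9 organizer and marginal zone signals 5 were lower (5 adjusted over the list alone; adjusted p = 0.00341 with an estimated correlation), including spry1.L, an inhibitor of receptor tyrosine kinase signaling, which fell by 1.27 ± 0.11 (SE). Among 127 respiratory chain genes 24 were lower (29 adjusted over the list alone; adjusted p = 0.0764 with an estimated correlation), with ndufa8.L, cox7c.S and uqcrc1.L at -2.11 ± 0.25, -1.71 ± 0.24 and -1.07 ± 0.12 (SE). The change of uqcrc1.L was just short of 2-fold under quantile normalization (-0.97) and in experiment 2 alone (-0.95). The factor genes mycn.S, klf2.L and smad6.L changed by -1.70 ± 0.16, -1.37 ± 0.12 and -1.25 ± 0.14 (SE). The gene tbpl2.L, a TBP paralog of the oocyte, went from 39.8 ± 7.80 to 2.50 ± 1.29 (SD, n = 4). BMP-responsive and ventral genes had 4 of 18 higher and 3 lower (4 and 4 adjusted over the list alone; adjusted p = 0.0636 with an estimated correlation, downward although the mean was 0.19), and ectoderm genes 2 of 29 higher and 2 lower (2 and 2; adjusted p = 0.066 with an estimated correlation). Pou5f3, Sox and partner factors had 0 of 24 higher and 1 lower (1 and 1 adjusted over the list alone; adjusted p = 0.867). Splicing factors had 0 of 109 called (0 adjusted over the list alone) while their camera test was upward (median 0.24, adjusted p = 0.00316 with an estimated correlation). Histones had 0 of 29 higher and 1 lower (0 and 1 adjusted over the list alone; adjusted p = 0.0611 upward, 0.0128 with the replicate block). Ribosomal proteins had 3 of 144 lower (3 adjusted over the list alone; adjusted p = 0.0964). Chromatin genes had 0 of 45 called (0 adjusted over the list alone), with an adjusted p of 0.0292 upward, 0.281 with an estimated correlation and 0.732 downward under quantile normalization.

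A few zygotic genes also appeared in flowthrough RNA at low level. Mesendoderm factors had 13 of 21 higher and 3 lower (13 and 3 adjusted over the list alone; adjusted p = 0.00356 with an estimated correlation). The genes gs17.L, bix1.2.L and foxi4.2.S were listed at 0 in the 4 libraries of 5 hpf and appeared by 9 hpf, gs17.L at 60, 37, 59 and 63, bix1.2.L at 41.8 ± 15.5 and foxi4.2.S at 41.0 ± 20.2 (SD, n = 4). The level of mix1.L was 45.0 ± 11.8 at 9 hpf (SD, n = 4). The arginine tRNA gene trnar-ucg_gene38518 was also at 0 at 5 hpf and at 95.5 ± 35.3 at 9 hpf (SD, n = 4), and is uncertain because another copy held the same values. In experiment 1 alone 12 genes were higher and 260 lower, and in experiment 2 alone 22 and 331. The gene bix1.2.L lost its call in experiment 1 alone (adjusted p = 0.0711) and junb.L in experiment 2 alone (adjusted p = 0.0806).

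Total RNA gained the same kinds of regulators. At 9 hpf 1346 genes were higher and 431 lower than at 5 hpf among 21534 tested, after 14, 242 and 881 higher at 6, 7 and 8 hpf. The gene ventx2.2.S rose to 2042 ± 0.707 (SD, n = 2), a log2 change of 11.00 ± 0.47 (SE, adjusted p = 1.08e-06), and mix1.L to 2276 ± 64.3 (SD, n = 2), a change of 9.65 ± 0.43 (SE, adjusted p = 1.08e-06). The Wnt-responsive factor sp5l.L, eomes.S, mixer.S, fgf8.L, id3.L and tfap2a.L were listed at 0 in the 4 libraries of 5 hpf and were at 1242 ± 41.7, 1204 ± 180, 582 ± 3.54, 542 ± 6.36, 1176 ± 68.6 and 376 ± 38.2 at 9 hpf (SD, n = 2). Changes of pou5f3.2.L, gs17.L, foxi4.2.S, the TGF-beta ligand gene gdf3.S and the endoderm factor sox17b.1.S were 3.94 ± 0.35, 11.07 ± 0.49, 10.48 ± 0.79, 9.49 ± 0.62 and 6.61 ± 0.34 (SE). With the experiment term, changes of total RNA rest on the 5 hpf libraries of experiment 1. In those gdf3.S was listed at 0, so the size of its change depends on the pseudocount, as for any other gene at 0 there. The genes btg4.S, btg4.L and cdk1.S changed by -1.47 ± 0.09, -1.95 ± 0.16 and -2.26 ± 0.21 on the log2 scale (SE, adjusted p = 4.91e-06, 2.49e-05 and 7.33e-05).

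In total RNA 14 of 17 nodal ligands and early Wnt targets were higher at 9 hpf, 41 of 50 mesendoderm factors, 19 of 27 organizer and marginal zone signals, 19 of 32 BMP-responsive and ventral genes and 17 of 44 ectoderm genes, with 1 BMP list member lower and 0 in the others (16, 43, 22, 22 and 18 adjusted over the list alone; adjusted p = 0.0014, 1.99e-05, 0.00089, 0.00445 and 0.0243 with an estimated correlation). Pou5f3, Sox and partner factors had 10 of 31 higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation). Immediate early genes had 12 of 42 higher and 4 lower (12 and 4 adjusted over the list alone; adjusted p = 0.0777); the phosphatase gene dusp1.S rose by 3.98 ± 0.41 (SE). Cell cycle regulators had 6 of 74 higher and 10 lower (7 and 10 adjusted over the list alone; adjusted p = 0.319 with an estimated correlation), with the CDK inhibitor gene cdkn1a.L rising by 4.55 ± 0.47 (SE). Cleared maternal messages had 11 of 40 lower (11 adjusted over the list alone; adjusted p = 0.0373 with an estimated correlation). Histones had 5 of 30 higher and splicing factors 4 of 109 (5 and 4 adjusted over the list alone; adjusted p = 0.0221 and 0.0142 with an estimated correlation). Of these srsf2.L rose by 1.92 ± 0.17 (SE), and h3c14.L by 1.19 ± 0.24 (SE), or 0.17 under quantile normalization. Without 5 hpf library 1, 9 hpf library 2 or all of replicate 1 its adjusted p was 0.0645, 0.0645 and 0.127. Respiratory chain genes had 19 of 130 lower and ribosomal proteins 1 of 145 (25 and 0 adjusted over the list alone; adjusted p = 0.238 and 0.647 with an estimated correlation); for ribosomal proteins it was 0.00248 at the preset correlation and 0.0720 under quantile normalization. RNA polymerase II and Mediator subunits had 1 of 105 higher and 2 lower (1 and 2 adjusted over the list alone; adjusted p = 0.0243 with an estimated correlation, 0.0559 under quantile normalization). The elongation factor gene eef1a1.S rose by 2.19 ± 0.33 (SE), with an adjusted p of 0.0637 without replicate 2. The histone deacetylase gene hdac2.L fell by 1.38 ± 0.18 (SE), with an adjusted p of 0.0532 without replicate 1.

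The largest drops in total RNA that the naming rule took were those of cmc1.L, ndufa1.S, use1.L, arl3.S, anapc10.L, a subunit of the anaphase-promoting complex, and mad2l1.L, with log2 changes of -3.44 ± 0.59, -2.78 ± 0.53, -2.64 ± 0.31, -2.59 ± 0.25, -2.47 ± 0.27 and -2.47 ± 0.61 (SE). Adjusted p-values rose to 0.14 for cmc1.L without replicate 2, to 0.179 for ndufa1.S without replicate 1 (0.0637 without its 9 hpf library alone), and to 0.229 and 0.143 for mad2l1.L without replicate 1 or 2. For mad2l1.L they were 0.0506 and 0.17 without 5 hpf library 1 or 2 and 0.196 without 9 hpf library 1. The respiratory gene atp5f1a.L changed by -1.03 ± 0.11 (SE), by -0.91 without 9 hpf library 1, by -0.98 without 5 hpf library 2 and by -0.96 without replicate 1. At 6 and 7 hpf limma called 0 genes lower in total RNA, and 55 at 8 hpf. With the replicate block these counts were 2 at 7 hpf and 113 at 8 hpf. In the limma fit 101 and 247 genes had an unadjusted p under 0.05 for lower values at 6 and 7 hpf. That is fewer than chance would give among the genes tested. Higher values at 6 hpf were also fewer than that, with 286 genes, so the shortfall does not show that no gene fell. Without 6 hpf library 2 there were 2 lower genes at 6 hpf, and without 7 hpf library 1 there was 1 at 7 hpf. Quantile normalization moved the higher share at 9 hpf from 75.7% to 61.3% (1092 and 690). All total RNA after 5 hpf came from 2 libraries per time of experiment 1, so the count of 1346 was 555 or 644 without all libraries of replicate 1 or 2. The 431 lower genes became 240 without 5 hpf library 2, slightly fewer than that without 9 hpf library 1, and 137 or 241 without replicate 1 or 2. The higher counts at 8 hpf were 548 and 574 without 8 hpf library 1 or 2, 570 without 5 hpf library 2 and 302 or 278 without replicate 1 or 2. The 55 lower were 32, 10, 7, 0 and 6 without 5 hpf library 1, 8 hpf library 1, 5 hpf library 2, replicate 1 or replicate 2. At 7 hpf the 242 were 125, 83, 112, 117, 32 and 50 without 5 hpf library 1, 7 hpf library 1, 5 hpf library 2, 7 hpf library 2, replicate 1 or replicate 2. At 6 hpf the 14 were 1, 7, 2, 2 and 1 without 6 hpf library 1 or 2, 5 hpf library 2, replicate 1 or replicate 2.

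Genes that rose in bead RNA largely overlapped those that rose in total RNA. Among 20025 genes tested in both, 1053 were higher in bead and 1100 in total RNA at 9 hpf, and 694 in both, where independent lists would share 57.8. Lower genes numbered 296 and 425 with 108 in both, against 6.28. The 694 became 333 or 361 without replicate 1 or 2. Bead and total RNA libraries of a replicate number come from the same clutch. Flowthrough and total RNA shared 307 lower genes of 757 and 426 among 19115, against 16.9.

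L and S copies of a gene often rose together in bead RNA. Of 5030 pairs with both copies tested 130 had both copies higher at 9 hpf, 103 the L copy alone and 79 the S copy alone. The odds ratio of both copies being called was 75.2. L alone against S alone gave p = 0.0879 in a two-sided exact binomial test, and in total RNA, chosen after seeing the data, 86 against 57 of 5174 pairs gave p = 0.0189 in the same exact test.

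Between the egg and 5 hpf limma called few genes in total RNA. Of 21534 genes 51 were higher at 5 hpf and 61 lower, and 1186 and 1608 had an unadjusted p under 0.05. In simulated data 30% of 2-fold changes were called. The kinase gene pak5.S was listed at 0 in both eggs and was at 68, 80, 57 and 86 at 5 hpf, and the replication factor gene cdc45.S was at 5 and 9 in eggs and 268, 190, 285 and 214 at 5 hpf, a log2 change of 5.00 ± 0.31 (SE, adjusted p = 7.16e-05). The genes tmem164.S and dbh.S rose by 5.44 ± 0.37 and 5.21 ± 0.39 (SE). The kinase gene wee1.S, which holds back mitosis, rose by 1.42 ± 0.24 (SE, adjusted p = 0.0286). Values of l1cam.S were 27 and 62 in experiment 1 and 2337 and 2095 in experiment 2 at 5 hpf, against 82 and 99 in the eggs.

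Lower at 5 hpf than in the egg were the checkpoint gene chfr.S, at 216 and 88 in the eggs and 0, 0, 0 and 5 at 5 hpf, the receptor kinase gene tek.S, at 206 and 396 against 1, 1, 8 and 6, scyl3.S, at 114 and 82 against 1, 4, 2 and 6, and the homeobox gene otx2.S, at 52 and 126 against 13, 15, 8 and 9. The stress gene gadd45a.S fell by 2.43 ± 0.34 (SE, adjusted p = 0.0155). Of 145 ribosomal protein genes 4 were lower and of 130 respiratory chain genes 3 (9 and 6 adjusted over the list alone; adjusted p = 0.409 and 0.44 with an estimated correlation). Examples are rps2.L, ndufb2.S and atp5mf.S, with changes of -2.39 ± 0.39, -1.43 ± 0.24 and -1.38 ± 0.24 (SE), and the translation factor gene eif5.S fell by 1.02 ± 0.16 (SE). Ectoderm genes and splicing factors, with 0 of 44 and 0 of 109 called (0 higher and 2 lower, and 0, adjusted over the list alone), and immediate early genes and cleared maternal messages, with 1 of 42 and 0 of 40 lower (6 and 0 adjusted over the list alone), passed at the preset correlation and not with an estimated one (adjusted p = 0.409, 0.409, 0.409 and 0.525). Lists that passed at the preset correlation included some that were higher at 5 hpf, so a pass does not by itself mean lower. Ectoderm genes went from 0.0112 to 0.0887 under quantile normalization, and chromatin genes from 0.355 to 0.0381 downward, with 0 of 45 called (1 lower adjusted over the list alone).

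All 15 genes named here for eggs lost their call in at least 1 alternative, in 111 of 330 values, and in simulated data with these spreads 23.7% of calls were unchanged genes. With the experiment term the comparison rests on the 2 egg and the 2 5 hpf libraries of experiment 2. On those libraries alone, a fit chosen after seeing the data, 3 genes were higher and 0 lower. Fitting only the groups compared gave 7 and 0. The higher count was 89 or 134 without egg library 1 or 2, 18 without 5 hpf library 3 or 4, alone or with all of that replicate number, and 100 without replicate 2. The lower count was 35 or 38 without egg library 1 or 2, 6 or 10 without 5 hpf library 3 or 4, and 20 or 19 without replicate 1 or 2.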

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

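Among the tests below, those of less carry-over in abundant genes, of shared clutches, of the same library entered again and of low recovery in experiment 2 were chosen after the result was seen.

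Flowthrough and total libraries of replicates 1 and 3, and of replicates 2 and 4, resembled each other across the 2 experiments, although the design text gives 4 clutches. Their correlations were 0.959 to 0.981, against 0.915 to 0.942 for the other pairs, in 6 of 6 groups of 4 libraries, a count that restates the likeness and does not test shared clutches or parents against another cause. In flowthrough 19 genes were at 50 or more in all 10 libraries of 1 parity and at 1 or less in all 10 of the other (7 high in odd, 12 in even replicates); all 19 were parted in total RNA too and 6 in bead RNA. Of the 19, 6 were at 50 or more in 1 egg library and at 1 or less in the other. The bound set beforehand against handling of the libraries was 20, missed by 1 and not moved. By that bound shared clutches or parents and handling were not told apart, and true replication may be lower than 4. The same library entered again is argued against: in each of the 12 same-parity pairs at least 8 genes with a mean of 1000 or more differed by over 1.5-fold, and the most abundant gene by 1.63 to 2.82-fold. That test replaced 2 earlier ones after their values were seen, each the share of such genes that differed by over 20%, with bounds of 1 and 5. The share in the closest pair of any libraries, replicate 4 of flowthrough at 5 and 6 hpf, was 0.453%, within the bound for a repeated entry. That in the closest pair of 1 group was 1.85%, between the bounds.

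At 9 hpf 4075 genes were lower on the beads than in flowthrough. Their median log2 difference was -0.22 in experiment 1 (quartiles -0.49 and 0.01) and -5.24 in experiment 2, and 3493 of them were listed at 0 in an experiment 2 bead library, against 118 in experiment 1, values that low recovery of RNA in the bead libraries of experiment 2 needs. In bead libraries of 9 hpf the smallest values above 0 were 1 in replicate 3 and 3 in replicate 4, and the commonest were 2 and 4. Of 11548 abundant genes 12.1% and 21.8% were listed at 0 there. Values of 0 in genes far above such small values argue against low sequencing depth alone at 9 hpf. Depth itself was not measured. Less carry-over of unlabelled RNA in experiment 2 would raise zygotic genes there; the 1346 genes higher in total RNA differed by a median of -1.40 between the experiments, with quartiles of -3.40 and 0.10, and 50% of them were listed at 0. The 83 genes at 1000 or more in total RNA differed by a median of -0.83 (quartiles -1.36 and -0.03). That is under the bound of 0, which was set beforehand for all 1346 genes and not for these. Total RNA of 9 hpf, which chose them, came from experiment 1 alone. The sign of such medians changed with the libraries that chose the genes, so this one does not decide. Chosen by bead libraries, which enter the difference, the medians were -0.73 by experiment 1 (147 genes), -0.29 by the mean of all (159 genes, quartiles -0.92 and 1.56) and 0.40 by experiment 2 (140 genes, quartiles -0.66 and 2.42). Over the 1346 genes the median of -1.40 is also under the bound of 0, which was set beforehand on the median alone. It is not taken to decide, because values of 0 lower it and the quartiles lie on both sides of 0. This reading by quartiles was not part of the bound. Over the 1346 genes less carry-over therefore cannot be told apart from low recovery. No biological explanation was tested.

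At 5 hpf 94 genes were higher on the beads, with a median log2 difference of 0.14 in experiment 1 and 2.50 in experiment 2. Transcription before 6 hpf predicted a rise in total RNA by 9 hpf of 0.5 or more, and 0.1 or less if not; the median over 89 genes was 0.105, and 15 of them were called higher. Binding to the beads without label predicted a constant bead to flowthrough ratio, and a change over 1 if not; the median change was 0.943. Both medians fall between their bounds, so the explanations cannot be told apart for these genes as a set. The set is mixed: the quartiles in total RNA were 0.0007 and 0.322, while mix1.L rose by 9.65 and polr2a.L by 0.35. The ratio change also reuses the 5 hpf values by which the genes were chosen. The cause of the difference between the experiments was not tested.

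The 8 libraries of each comparison can be split into groups of 4 in 35 ways. The real split of bead against flowthrough was exceeded by another at 5 hpf (410 calls, highest other 465) and at 6 hpf (735, 740), 2 of 35 splits in each, so chance is not excluded there. It was highest at 7, 8 and 9 hpf (1387, 3203 and 6089 calls, highest others 851, 2042 and 4329), 1 of 35 each. The high other splits exchanged 1 bead with 1 flowthrough library of experiment 1. The real split was also highest for the ratio change (1027, highest other 1), flowthrough (798, 1) and bead RNA at 6, 7, 8 and 9 hpf (21, 259, 663 and 1504, highest others 4, 1, 0 and 0). A share of 1 in 35 is the smallest that this test can give, and these splits ignore the pairs of same-numbered libraries. Among the 8 splits that part every pair the real split was highest in all 11 comparisons, and 8 are too few for a share under 0.05. The splits therefore rank the real grouping first in these comparisons without excluding chance. Total RNA and eggs had groups of 2 libraries and were not split.

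The bead to flowthrough ratio rose for 992 genes and fell for 35 between 5 and 9 hpf in a test of the difference between the 2 changes.

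Of 231 groups of libraries or gene values examined, 23 (9.96%) held a library far from the others. Where the others were all at 0, any value above 0 counted as far, so this share is not comparable with chance. In bead RNA at 5 hpf, eomes.S was at 1 in replicate 2, and foxi4.2.S, mixer.L, eomes.L and dll1.S at 19, 4, 1 and 1 in replicate 1, against 0 in the others. There plk1.S was at 2333 in replicate 3, against 3082 to 3228. At 9 hpf bead replicate 4 held flrt3.S at 838, against 273 to 305, and dnmt1.S at 2788, against 2434 to 2487. In flowthrough at 9 hpf, grhl3.S, lpar6.L and nodal2.L were at 8, 1 and 1 in replicate 4, and flrt3.L, dlx5.S and cer1.S at 1, 5 and 6 in replicate 3, against 0 in the others. There znf750.L was at 7 in replicate 3, against 0 to 1, foxa4.L at 19 in replicate 4, against 2 to 3, hnrnpa2b1.L at 2359 in replicate 3, against 2515 to 2533, and gs17.L at 37 in replicate 2, against 59 to 63. In flowthrough at 5 hpf mix1.L was at 1 in replicate 4, against 0. In total RNA at 5 hpf ndufa1.S was at 211 in replicate 4, against 148 to 155, eif5.S at 312 in replicate 4, against 281 to 285, chfr.S at 5 in replicate 4, against 0, and gdf3.S at 2 in replicate 3, against 0.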

How the results depend on the processing

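Library weights, a term for odd and even replicates, averaged replicates, fits without the bead libraries of experiment 2, eggs with experiment 2 alone, and the list, onset and overlap settings added to them were tests chosen after the result was seen. The planned test on counts was not run, because the values are not counts. Of 3282 values of the genes named under an alternative 3092 kept their direction and call, 189 lost the call and 1 was reversed. For eggs 111 of 330 lost it, against 32 of 918 for bead RNA, 25 of 672 for bead against flowthrough, 4 of 724 for flowthrough and 17 of 638 for total RNA. Counts are given as higher or lower genes of each comparison with 5 hpf unless said otherwise, and the cause was not tested except where said.

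Under quantile normalization the lower genes were 3, 42 and 562 in bead RNA at 7, 8 and 9 hpf, and 123, 174, 331, 934 and 2204 on beads against flowthrough at 5 to 9 hpf, with 304 higher at 6 hpf. The ratio change had 108 lower, flowthrough 61 higher and 476 lower, total RNA 97 and 690 lower at 8 and 9 hpf, and ep300.L reversed on beads against flowthrough at 9 hpf, to -0.27. Lists called lower became 5 in bead RNA, 7 on beads against flowthrough and 3 in total RNA, and lists higher in 5 hpf against egg 1. With an estimated correlation, lists lower became 1, 0, 4, 2 and 0 in bead RNA, bead against flowthrough, flowthrough, total RNA and eggs, and lists higher in eggs 0.

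Without the experiment term bead RNA had 10, 162, 413 and 745 higher at 6 to 9 hpf and 1 and 63 lower at 8 and 9 hpf. Beads against flowthrough had 4, 47, 380 and 859 higher at 5 to 8 hpf and 2, 6, 12, 38 and 967 lower at 5 to 9 hpf. The ratio change had 1 lower, total RNA 2 and 90 lower at 7 and 8 hpf, and 5 hpf against egg 99 higher and 143 lower, with 1 list higher. With the replicate block flowthrough had 63 higher and total RNA 2 and 113 lower at 7 and 8 hpf; it moved no other count past 1.5 times. The block brought the chromatin list in bead RNA from an adjusted p of 0.0653 to 0.0367 and histones in flowthrough from 0.0611 to 0.0128, and changed no other list call. With the odd and even term these were 62, 2 and 122, and total RNA at 6 hpf had 22 higher.

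Fitting the compared groups alone, which leaves fewer libraries to estimate spread, gave 1 higher at 6 hpf and 1 and 53 lower at 7 and 9 hpf in bead RNA, 1102 lower on beads against flowthrough at 6 hpf, 1 lower in the ratio change, 1 and 12 higher at 6 and 7 hpf and 19 lower at 8 hpf in total RNA, and 7 higher and 0 lower against eggs. In experiment 1 alone, with fewer libraries, bead RNA had 32, 534 and 1050 higher at 6 to 8 hpf and 27 lower at 8 hpf. Beads against flowthrough had 17 and 75 higher at 5 and 6 hpf and 6, 8, 16, 19 and 72 lower at 5 to 9 hpf. The ratio change had 7 lower, flowthrough 12 higher and 260 lower, and the onset classes of 6 and 7 hpf 32 and 495 genes. In experiment 2 alone bead RNA had 2, 21, 55 and 224 higher at 6 to 9 hpf and 0 and 56 lower at 8 and 9 hpf. Beads against flowthrough had 305 and 381 higher at 5 and 6 hpf. The ratio change had 331 higher and 267 lower, flowthrough 22 and 331, and the onset classes 2, 19, 34 and 169 genes. On the experiment 2 libraries 5 hpf against egg had 3 higher and 0 lower.

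Library weights gave 91, 855, 1581 and 1999 higher at 6 to 9 hpf and 2, 9 and 78 lower at 6 to 8 hpf in bead RNA. Beads against flowthrough had 172 and 333 higher at 5 and 6 hpf and 2452, 2196, 2231, 2732 and 2479 lower at 5 to 9 hpf, and the ratio change 1664 higher and 14 lower. Averaging replicates 1 with 3 and 2 with 4, which leaves 2 values per group, gave 6 and 129 higher at 6 and 7 hpf and 4 lower at 8 hpf in bead RNA. Beads against flowthrough had 53 higher at 5 hpf and 86, 225 and 318 lower at 5 to 7 hpf. The ratio change had 297 lower, and flowthrough 23 higher and 380 lower. Without the bead libraries of experiment 2 beads against flowthrough had 27 higher at 5 hpf and 45, 21, 74, 46 and 138 lower at 5 to 9 hpf, and the ratio change 1652 and 22.

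With no filter bead RNA had 4 and 191 lower at 8 and 9 hpf, the ratio change 14 lower, flowthrough 127 higher, and total RNA 1 lower at 7 hpf and 2098 higher at 9 hpf. A filter of at least 50, with fewer genes tested, gave 144, 301 and 318 lower on beads against flowthrough at 5 to 7 hpf, 5 higher in flowthrough, and 478 and 641 higher in total RNA at 8 and 9 hpf. A pseudocount of 8 gave 13 higher at 6 hpf and 14 lower at 8 hpf in bead RNA, 354 lower on beads against flowthrough at 6 hpf, and 5 higher in total RNA at 6 hpf. With no fold threshold, which adds smaller changes by construction, bead RNA had 19 lower at 8 hpf, beads against flowthrough 351 and 461 higher at 5 and 6 hpf, flowthrough 1218 higher and 2486 lower, and total RNA 2, 186 and 1018 lower at 7 to 9 hpf. Homeolog pairs with means of at least 50 in both copies, which are fewer, had 60 with the L copy and 46 with the S copy alone. Rescaling by trimmed means and a pseudocount of 0.5 moved no count past 1.5 times.

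Leaving out 1 library or 1 replicate number leaves fewer libraries. It gave, lowest and highest, 13 to 20 higher at 6 hpf, 145 to 226 at 7 hpf, 0 to 3 lower at 7 hpf, 0 to 24 lower at 8 hpf and 87 to 622 lower at 9 hpf in bead RNA. Beads against flowthrough had 58 to 139 higher at 5 hpf, and 107 to 604, 173 to 583, 235 to 901, 400 to 3091 and 1511 to 4857 lower at 5 to 9 hpf. The ratio change had 1 to 505 lower. Total RNA had 1 to 14, 32 to 225, 278 to 831 and 555 to 1314 higher at 6 to 9 hpf and 0 to 2, 0 to 1, 0 to 49 and 137 to 474 lower. Against eggs 18 to 134 were higher and 6 to 47 lower. The onset class of 7 hpf held 128 to 161 genes and the overlap of bead and total RNA 333 to 361. Where a group is left with 1 library, limma takes its spread from the other groups.

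Values of 0 limit the bead libraries of experiment 2, where up to 21.8% of 11548 abundant genes were listed at 0. In simulated data 42.8% of 4-fold changes and 7.60% of 2-fold changes of bead RNA were called, so genes that were not called may have changed: in experiment 1 alone 534 were higher at 7 hpf.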

Other observations

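All of the genes in the first 2 paragraphs were chosen after their values were seen. Single members of the immediate early list went different ways, and the list as a whole did not pass in bead RNA with an estimated correlation (adjusted p = 0.239). The phosphatase gene dusp5.L, an inhibitor of ERK, rose by 8.14 ± 0.97 in bead RNA at 9 against 5 hpf (SE, adjusted p = 3.89e-06) and by 6.07 ± 0.73 in total RNA (SE, adjusted p = 0.000336). The antiproliferative gene btg1.S rose by 1.48 ± 0.25 in bead RNA (SE, adjusted p = 0.000245). The DNA damage gene gadd45a.S rose by 5.88 ± 1.16 in bead RNA (SE, adjusted p = 0.00141) and changed by -2.38 ± 0.67 in flowthrough (SE, adjusted p = 0.0161), a decline that was not called under quantile normalization. In contrast ccn1.S changed by -2.75 ± 0.56 in flowthrough (SE, adjusted p = 0.00204) and by -1.93 ± 0.40 in total RNA (SE, adjusted p = 0.00938), and was not called in bead RNA (adjusted p = 0.163). The maternal Wnt ligand gene wnt11b.L rose by 1.65 ± 0.35 in bead RNA (SE, adjusted p = 0.00294) and changed by -1.19 ± 0.17 in flowthrough (SE, adjusted p = 4.05e-05), while its total RNA level was 684 ± 89.7 at 5 hpf (SD, n = 4) and 1138 ± 123 at 9 hpf (SD, n = 2).

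Single members of the lists of transcription, translation and cell cycle genes gained bead RNA by 9 hpf, although the lists did not rise (adjusted p = 0.564 and 0.796 for the first 2, and 4 cell cycle genes higher against 11 lower). The kinase gene cdk9.L, which releases paused RNA polymerase II, rose by 2.44 ± 0.32 (SE, adjusted p = 1.11e-05), and the bromodomain gene brd2.S by 1.86 ± 0.37 (SE, adjusted p = 0.00155). The elongation factor genes eef1a1.S and eef1a1o.S rose by 3.06 ± 0.47 and 1.92 ± 0.28 (SE), and eef1a1o.L was not called (adjusted p = 0.406). The CDK inhibitor gene cdkn1a.L and the phosphatase gene cdc25b.S rose by 6.10 ± 1.51 and 5.53 ± 1.17 (SE, adjusted p = 0.0115 and 0.00300). In total RNA cdkn1a.L and the cyclin gene ccne2.L rose by 4.55 ± 0.47 and 1.54 ± 0.17 (SE, adjusted p = 0.000135 and 0.000184). Of the control lists, rax.L was called in bead RNA (adjusted p = 0.0399), at 65.8 ± 78.3 at 9 hpf (SD, n = 4), and ckm.L was not (adjusted p = 0.318). In total RNA rax.L, ckm.L and star.L were called, by 3.26 ± 0.94, 3.63 ± 0.94 and 3.46 ± 0.74 (SE, adjusted p = 0.0479, 0.0290 and 0.0113), but none of them under quantile normalization.

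The first 4 components of the libraries held 36.0%, 12.1%, 8.76% and 5.80% of the variance.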
